A study of Mus musculus with 24 samples.

How the data were processed

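RNA was extracted with Trizol and sequencing libraries of messenger RNA were made with oligo(dT) capture, per the labels' protocols. The values used here are the FPKM (fragments per kilobase of exon, scaled to the mapped fragments of a library) that the authors deposited for 54532 genes in 24 libraries. The submitters' processing notes name HISAT2, STAR, featureCounts, StringTie, edgeR, DESeq and STAR-Fusion with the mouse builds mm10 and GRCm38; their roles, order, versions and the strand setting are not given in the sources used here. Without strand, reads of overlapping antisense genes cannot be told apart, and reads shared by near-identical genes can be split between them. Gene identifiers were matched to GENCODE M21 (GRCm38), which named 54495 of them and left 37 unmatched, and coordinates come from that annotation.

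The deposited FPKM values kept the depth. For 26186 of 27013 genes above 0 (96.9%), multiplying by the exon length and the value of 1 read gave whole reads in every library, with a tolerance of 0.05, and 96.4 to 96.7% of values per library were whole. The recovered depth was 16.6 to 25.2 M reads (M, 1e6) per library. The gene with the largest share of summed FPKM, Gm23935, has 57 bases of exon and took 4.38 to 18.6% of a library's sum, so scaling to a common sum (TPM) moves all other genes with it. The 36 pairs of libraries within groups differed by more than sampling noise, with chi-square per degree of freedom from 2.81 to 23.5, and 0 pairs were identical.

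Groups were taken from the labels, 4 libraries in each of 6. No library was left out of the main analysis. Genes with an FPKM of at least 1 in at least 4 of 24 libraries were kept, 11377 in all, and tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in 1 fit of 6 group means with a mean-variance trend. There were 11 comparisons: both treatments in each genotype, the genotypes within each treatment, the treatments against each other in each genotype, and the genotype by treatment interactions. Calls are at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and n counts libraries. In this fit the SE of a gene rests on 1 spread shared by all 6 groups, so it does not show how uneven a single group is. These tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, except where the text says otherwise.

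The rule named Trem2, up to 10 genes with the largest rise and 10 with the largest fall among those called with a mean FPKM of at least 5 in the higher group and no overlap between the groups' libraries. It also named up to 4 members of each list with the smallest adjusted p, the 10 smallest p-values of each interaction, the S1P receptors and the genes next to Trem2. Predicted genes, clones and mitochondrial genes were left out of the largest changes. The text gives a selection of the genes so named, and the result of 1 of them is not reported here.

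The 27 gene lists cover the lipid-associated macrophage program, efferocytosis, S1P receptors and metabolism, NF-kB, type I interferon, alternative activation, cholesterol synthesis and uptake, LXR targets, fatty acid oxidation, cell cycle, integrated stress, NRF2, glycolysis and hypoxia. Others cover the respiratory chain, lysosome, antigen presentation, matrix mediators, genes next to Trem2, sex-linked transcripts, core macrophage genes, and markers of hepatocytes, fibroblasts, granulocytes, monocytes, dendritic cells, osteoclasts and lymphoid, mast or erythroid cells. Aldoa has 2 gene identifiers and its first was used. Each list with more than 1 gene kept was tested with camera (limma) at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. The fibroblast list had 0 genes kept and the lymphoid, mast or erythroid list 1, so camera was not run on them. Median, mean and camera direction differed in sign in 54 of 275 list tests, 0 of them called.

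The test was checked on simulated data made from the means of these libraries. The changed genes were drawn only from those with a mean above an FPKM of about 5, so recovery of lower genes was not tested. With 50 genes changed at each size, the WT ACM comparison recovered 92% at a log2 change of 0.5, 98% at 1, and 100% at 2 and 4, with 14 calls among unchanged genes. The ACM interaction recovered 84%, 98%, 100% and 100%, with 11. A list moved in the simulation gave a camera adjusted p of 9.03e-121, with 0 called among the other lists that share no gene with it. Genes were drawn independently of each other, so this does not test the preset correlation. Shared controls were handled by simulating unchanged groups against the same controls, 20 times, and by splitting the controls 2 and 2 in all 6 ways.

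The alternatives were another pseudocount (0.1), no filter, a filter at FPKM 5, TPM scaling, quantile normalization, median scaling, robust empirical Bayes, library weights (arrayWeights), fits on only the groups compared, and leaving out each library in turn. Because the targeted gene went against the label of the library labelled KO untreated 81, a fit without that library was added after seeing the data, as was voom (limma) on the recovered reads. That library was kept in the main fit, and no sample was given another group.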

Results

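Messenger RNA was measured in macrophages grown for 7 days from the bone marrow of C57BL/6 mice in medium conditioned by L929 cells, a fibroblast line whose medium supplies macrophage growth factor. The cells came from wild-type (WT) mice or from mice with both copies of Trem2 knocked out (KO), Trem2 being a lipid-sensing surface receptor of macrophages that signals through the adaptor Tyrobp. They were left untreated or received, for 24 hours, S1P (sphingosine-1-phosphate, a lipid signal) at 500 nM or ACM, medium without serum taken from AML12 cells, a mouse hepatocyte line, after these had been made apoptotic with palmitate at 800 µM. The medium, any vehicle and the time in culture of the untreated cells are not given in the sources used here, so values against untreated cells do not separate an agent from its medium or vehicle. No group received palmitate alone or medium from AML12 cells without palmitate. Values for ACM therefore do not separate products of dying cells from other AML12 products or any palmitate left in the medium. The design crossed 2 genotypes with 3 treatments, with 4 libraries in each of 6 groups and 24 libraries in all. Between 16.6 and 25.2 M reads per library (M, 1e6) were recovered from the deposited FPKM values, and 10579 to 10892 genes per library reached an FPKM of 1. The labels name no batch, culture or animal, so the p-values below measure only the spread between these libraries, which may be technical. All libraries labelled WT have lower library numbers than those labelled KO, so genotype cannot be separated from any difference in when the libraries were prepared. Within each genotype every treatment has its own block of library numbers, so the same holds for treatment.

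**Figure D1:**
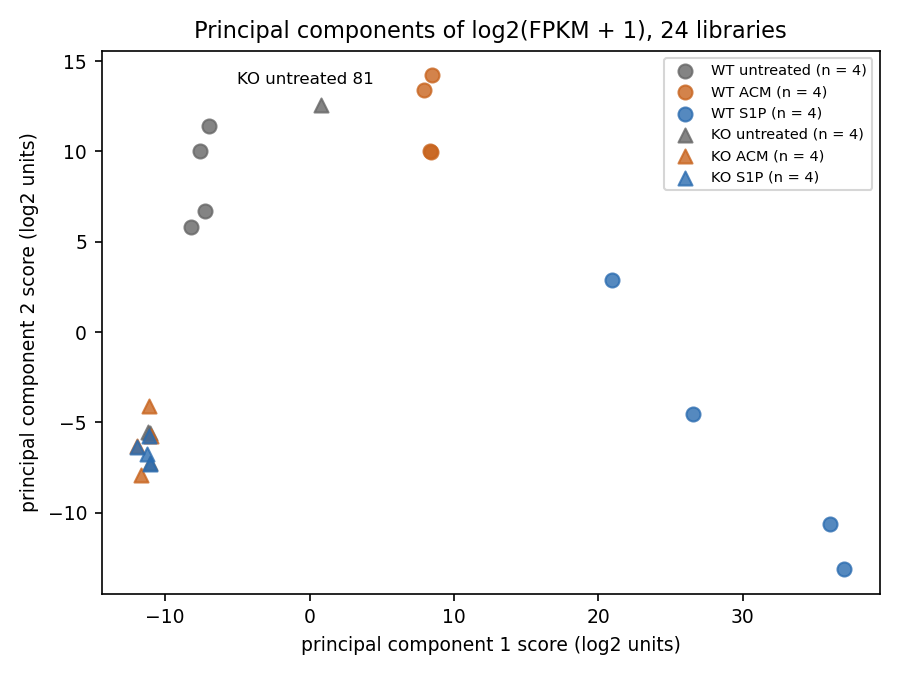
Scores of the 24 libraries on the first 2 principal components of log2(FPKM + 1) over 11377 genes, which hold 40.5% and 12.8% of the variance. Each point is 1 library, the colour gives the treatment and the shape the genotype. WT untreated libraries lie at -8.24 to -6.96 on the first component, WT ACM libraries at 7.94 to 8.44 and WT S1P libraries at 20.9 to 37.0. The other 11 KO libraries of all 3 treatments lie at -11.9 to -11.0 and the library labelled KO untreated 81 at 0.775.

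The targeted gene was examined first because it checks the genotype labels. Trem2 (ENSMUSG00000023992, GRCm38 chromosome 17, 48346401 to 48354147, protein coding) had a mean FPKM of 77.8 ± 3.72 in WT untreated, 90.1 ± 2.73 in WT ACM and 104 ± 4.7 in WT S1P cells (SD, n = 4 each). It was 39.2 ± 1.67 in KO ACM and 39.6 ± 0.983 in KO S1P cells (SD, n = 4 each). Transcript was thus still counted in the knockout, at a level -1.18 ± 0.14 (SE) log2 units below WT under ACM and -1.36 ± 0.14 below under S1P (limma adjusted p = 4.72e-06 and 7.49e-08). FPKM sums the whole gene, so it does not show which exons these reads cover, and the knockout allele is not given in the sources used here. In KO untreated cells the mean was 48.6 ± 20.8 (SD, n = 4), because the library labelled KO untreated 81 had an FPKM of 79.6, inside the WT untreated range of 74.5 to 82.7, while the 3 others had 35.7 to 40.2. Without the library labelled KO untreated 81 the mean was 38.2 ± 2.33 (SD, n = 3) and the difference from WT untreated went from -0.75 ± 0.14 to -1.01 ± 0.05 (adjusted p = 0.00794 and 3.7e-12). Counts of genes in comparisons with KO untreated cells are therefore given below with and without that library.

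Trem2 transcript was next compared between treatments in WT cells. Exact 2-sided permutation tests of log2(FPKM + 1) over 70 arrangements gave p = 0.0286, the smallest they can give, for WT ACM and for WT S1P against WT untreated, and for KO against WT cells under each treatment. With the library labelled KO untreated 81, these permutation tests gave p = 0.114 for KO untreated against WT untreated, and neither treatment passed them in KO cells. In limma the ACM difference, 0.21 ± 0.14, was not called (adjusted p = 0.328; 0.09 with TPM scaling, adjusted p = 0.652), and Trem2 rose with S1P by 0.41 ± 0.14 (adjusted p = 0.0218). The S1P call was lost with no filter (adjusted p = 0.0568) and without the library WT S1P 27 (0.38, adjusted p = 0.0545). Without the library labelled KO untreated 81, whose Trem2 value widens the shared error, the ACM difference passed, at 0.21 with adjusted p = 0.000858. In KO cells Trem2 did not pass, at -0.22 ± 0.14 with ACM and -0.21 ± 0.14 with S1P (0.04 ± 0.05 and 0.05 ± 0.05 without that library). The gene beside Trem2 on chromosome 17, Treml1 (48359916 to 48367176), was higher in KO than in WT cells under both treatments. Its FPKM was 1.68 ± 0.0913 in WT ACM and 7.89 ± 0.66 in KO ACM cells (SD, n = 4), a difference of 1.73 ± 0.32 (adjusted p = 0.00028). Under S1P the difference was 1.76 ± 0.32, and in untreated cells 1.78 ± 0.11 without the library labelled KO untreated 81 (adjusted p = 3.78e-10). With it the untreated difference was 1.21 ± 0.32 (limma adjusted p = 0.0467; exact permutation p = 0.143), a call lost in 13 of 19 other settings, with values from 0.94 (without KO untreated 80) to 1.78 when a library was left out. Trem1, an activating receptor of the same family, was also higher in KO ACM (1.11 ± 0.19) and KO S1P cells (1.83 ± 0.19). In WT cells its mean FPKM was 11.86 untreated, 8.145 with ACM and 5.665 with S1P, so these differences include the WT change with treatment. In KO untreated cells it was 14.76, and 17.38 without the library labelled KO untreated 81. Of the 15 genes tested next to Trem2, 3 were higher and 4 lower in KO ACM than in WT ACM cells, with a camera adjusted p of 0.723 for the list (0.783 with an estimated correlation).

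**Figure D2:**
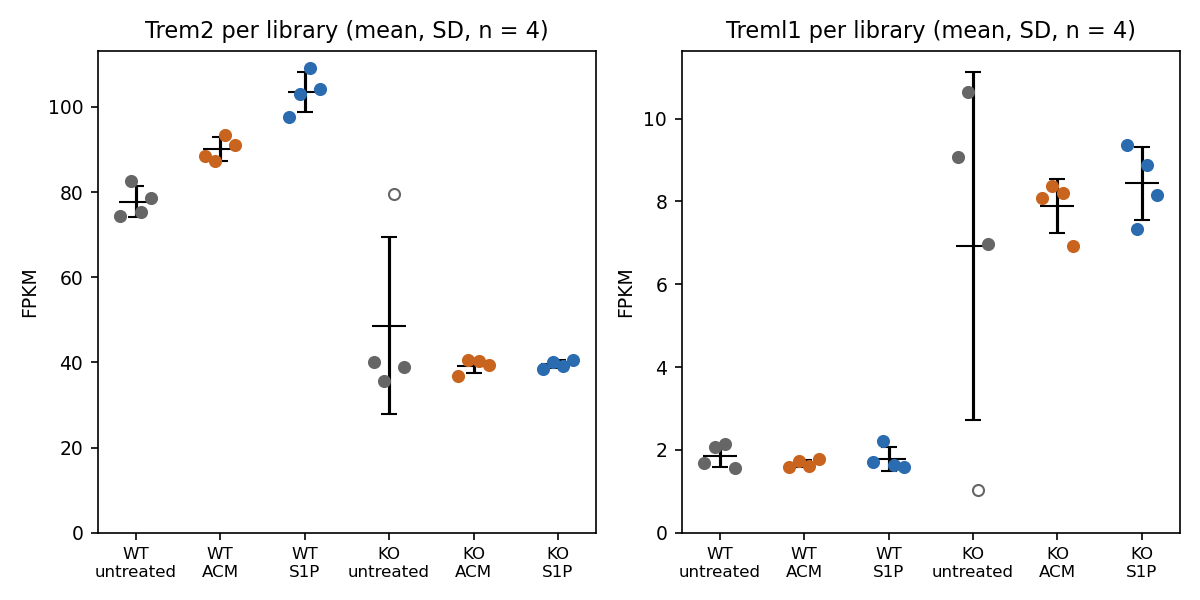
FPKM of Trem2 (left) and of Treml1 (right) in each library by group, on linear axes from 0; points are libraries and bars the mean with SD of 4 libraries. The open point is the library labelled KO untreated 81, with 79.6 for Trem2 and 1.03 for Treml1, where the other KO libraries have 35.7 to 40.7 for Trem2.

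The first comparison asked how WT macrophages respond to ACM. ACM raised Cdkn1c, a cyclin-dependent kinase inhibitor (2.52 ± 0.16 log2 units ± SE, n = 4 against 4), Mmp9, a gelatinase (2.13 ± 0.34), Procr, the protein C receptor (1.63 ± 0.15), Ddit3, which encodes the stress transcription factor CHOP (1.39 ± 0.15), and Acod1, the enzyme that makes itaconate (1.33 ± 0.23). Also raised was Plin2, a lipid droplet coat protein (1.28 ± 0.11). It lowered Mmp8, a collagenase (-1.96 ± 0.30), Ifitm1, an interferon-induced membrane protein (-1.88 ± 0.30), F13a1, a subunit of coagulation factor XIII (-1.57 ± 0.28), Ighm (-1.56 ± 0.12), Cbr2 (-1.24 ± 0.22) and Fcrls (-1.24 ± 0.19). Type I interferon response genes rose as a group, with 28 of 29 members higher and 0 lower (28 and 0 adjusted over the list alone), among them Irf7, the regulator of the response (1.04 ± 0.14), Ifit3 (1.20 ± 0.26) and Oas3 (0.69 ± 0.11). The median over the list was 0.65 and the camera adjusted p = 2.3e-17; adjusted p = 0.228 with an estimated correlation.

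Genes of cholesterol synthesis and uptake fell under ACM, 22 of 24 lower and 0 higher (23 and 0 adjusted over the list alone). They included Acat2 (-0.85 ± 0.06) and Fdft1, squalene synthase (-0.55 ± 0.05), and camera gave adjusted p = 3.49e-25 (0.00202 with an estimated correlation). LXR targets, the sterol-sensing nuclear receptor's genes, fell in 12 of 17 cases and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 2.62e-09, and 0.033 with an estimated correlation). The lowered members with the smallest adjusted p included Scd1 (-0.75 ± 0.04), Fasn (-0.81 ± 0.06) and Acaca (-0.28 ± 0.03), enzymes of fatty acid synthesis and desaturation. Among fatty acid oxidation and PPAR targets, 7 of 25 rose and 1 fell (8 and 1 adjusted over the list alone), with Cpt1a, which brings fatty acids into mitochondria (0.68 ± 0.05), and Hilpda (0.90 ± 0.10) among them. For fatty acid oxidation genes under ACM, camera gave adjusted p = 0.032 (0.319 with an estimated correlation). NRF2 and oxidative stress genes rose in 18 of 23 cases and fell in 0 (19 and 0 adjusted over the list alone), with Prdx1, a peroxiredoxin (0.74 ± 0.08), Gsr, glutathione reductase (0.62 ± 0.06), and Srxn1 (1.00 ± 0.12). Their camera adjusted p was 3.3e-15 (0.0706 with an estimated correlation). Of 26 integrated stress and ER stress genes 14 rose and 6 fell (15 and 8 adjusted over the list alone), with Ppp1r15a at 1.08 ± 0.13 and Psat1, of serine synthesis, at -0.48 ± 0.05. For stress response genes under ACM, camera gave adjusted p = 0.00534 (0.419 with an estimated correlation).

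Lysosomal genes rose in 17 of 33 cases and fell in 2 (18 and 3 adjusted over the list alone), including Lipa, the acid lipase (0.64 ± 0.09), and Ctsd, cathepsin D (0.32 ± 0.04, but 0.11 and not called with quantile normalization). For lysosomal genes under ACM, camera gave adjusted p = 4.27e-07 (0.033 with an estimated correlation). Antigen presentation genes rose in 13 of 23 and fell in 0 (14 and 1 adjusted over the list alone), with the class I genes H2-D1 (0.42 ± 0.05) and H2-K1 (0.32 ± 0.04) and their activator Nlrc5 (0.47 ± 0.05). For antigen presentation genes under ACM, camera gave adjusted p = 3.94e-06 (0.0521 with an estimated correlation). Cell cycle genes fell in 18 of 30 cases and rose in 0 (22 and 0 adjusted over the list alone), with Nusap1 at -0.41 ± 0.10 and Mki67 at -0.41 ± 0.12. For cell cycle genes under ACM, camera gave adjusted p = 2.21e-08 (0.352 with an estimated correlation). Of 23 NF-kB inflammatory genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), with the chemokine Ccl5 at 0.99 ± 0.13. For NF-kB genes under ACM, camera gave adjusted p = 0.00645 (0.16 with an estimated correlation). Of 28 glycolysis and hypoxia genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with Vegfa at 0.53 ± 0.06. For glycolysis and hypoxia genes under ACM, camera gave adjusted p = 3.83e-05 (0.319 with an estimated correlation). Over all genes limma called 2511 of 11377 changed, 1390 higher and 1121 lower, 41 of them by at least 1 log2 unit (2828 without the library labelled KO untreated 81). With values rescaled to TPM the split was 471 higher and 2751 lower, and that scaling moved the median of all genes by -0.11. With quantile normalization it was 1216 higher and 1287 lower.

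The next comparison asked how WT cells respond to S1P. Cdkn1c rose by 5.32 ± 0.16 log2 units (SE, n = 4 against 4), Serpinb9b, a protease inhibitor, by 3.97 ± 0.16, Procr by 3.49 ± 0.15, Slc7a11, the cystine importer, by 2.69 ± 0.12, and Nqo1, a quinone reductase, by 2.62 ± 0.11. Ddit3 rose by 2.47 ± 0.15. The WT S1P libraries were uneven, at 20.9 to 37.0 on the first principal component, which the shared SE does not show. Among the genes lowered most were Cbr2 (-2.59 ± 0.22), Mmp8 (-2.39 ± 0.30), Fcrls (-2.31 ± 0.19), F13a1 (-2.18 ± 0.28), Mrc1, the mannose receptor (-1.71 ± 0.13), and Stab1, a scavenger receptor (-1.66 ± 0.13). NRF2 and oxidative stress genes rose in 21 of 23 cases and fell in 0 (21 and 0 adjusted over the list alone), with a median of 1.04. Prdx1 rose by 2.10 ± 0.08, catalase (Cat) by 1.79 ± 0.08, Gstm1 by 1.78 ± 0.07 and Srxn1 by 2.57 ± 0.12. Camera gave this list adjusted p = 2.25e-17, and 0.116 with an estimated correlation. All 30 cell cycle genes fell (30 adjusted over the list alone), with a median of -1.18 and Cdc20 at -1.26 ± 0.11, Mcm4 at -1.02 ± 0.08 and Nusap1 at -1.26 ± 0.10. For cell cycle genes under S1P, camera gave adjusted p = 1.33e-17 (0.32 with an estimated correlation).

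All 24 genes of cholesterol synthesis and uptake fell as well (24 adjusted over the list alone), with Acat2 at -1.56 ± 0.06 and Idi1 at -1.36 ± 0.07, and camera adjusted p = 4.22e-18 (0.0112 with an estimated correlation). LXR targets fell in 10 of 17 cases and rose in 3 (11 and 3 adjusted over the list alone), with Fasn at -1.34 ± 0.06 and Scd1 at -0.92 ± 0.04. For LXR targets under S1P, camera gave adjusted p = 0.00345 (0.32 with an estimated correlation). Of 25 fatty acid oxidation and PPAR targets 11 rose and 1 fell (11 and 1 adjusted over the list alone), with Acot2 at 2.09 ± 0.12, Plin2 at 1.90 ± 0.11 and Cpt1a at 0.98 ± 0.05. For fatty acid oxidation genes under S1P, camera gave adjusted p = 0.0013 (0.21 with an estimated correlation). Of 26 integrated stress and ER stress genes 19 rose and 4 fell (19 and 4 adjusted over the list alone), with Ppp1r15a at 2.17 ± 0.13. For stress response genes under S1P, camera gave adjusted p = 7.7e-05 (0.366 with an estimated correlation). Efferocytosis genes, for the uptake of dead cells, fell in 13 of 23 cases and rose in 5 (13 and 5 adjusted over the list alone), Stab1 and the bridging ligands Gas6 (-1.30 ± 0.10) and Pros1 (-0.78 ± 0.06) falling and Thbs1 rising (1.48 ± 0.10). For efferocytosis genes under S1P, camera gave adjusted p = 0.0184 (0.515 with an estimated correlation). Core macrophage genes fell in 11 of 19 cases and rose in 5 (11 and 5 adjusted over the list alone), among them Cd163 (-0.89 ± 0.07), Maf (-1.16 ± 0.10) and Fcgr3 (-0.73 ± 0.06). For core macrophage genes under S1P, camera gave adjusted p = 0.0468 (0.601 with an estimated correlation). Lysosomal genes rose in 19 of 33 and fell in 10 (19 and 10 adjusted over the list alone), with Lipa at 0.99 ± 0.09 and Psap at 0.60 ± 0.04. For lysosomal genes under S1P, camera gave adjusted p = 0.00822 (0.32 with an estimated correlation). Glycolysis and hypoxia genes fell in 16 of 28 and rose in 5 (16 and 5 adjusted over the list alone), with Bnip3 at -0.70 ± 0.08 and Vegfa at 0.80 ± 0.06. For glycolysis and hypoxia genes under S1P, camera gave adjusted p = 0.0163 (0.601 with an estimated correlation). Type I interferon genes were not called as a list under S1P (5 of 29 higher and 2 lower, 3 and 1 adjusted over the list alone; camera adjusted p = 0.322), with Rsad2 at 0.84 ± 0.22 and Ifi27l2a at -0.50 ± 0.11. Over all genes limma called 5964 of 11377 changed, 2869 higher and 3095 lower, 327 of them by at least 1 log2 unit. The split was 3398 higher and 2677 lower with median scaling and 2008 and 3158 with TPM scaling, so which direction held more genes depends on the scaling.

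The 2 treatments were then set against each other in WT cells. ACM cells exceeded S1P cells in 25 of 29 type I interferon genes and fell below in 0 (26 and 0 adjusted over the list alone), for example by 0.87 ± 0.16 in Zbp1 and 0.53 ± 0.10 in Stat2. They were also higher in 30 of 30 cell cycle genes (Cdc20 1.05 ± 0.11) and 23 of 24 cholesterol genes. The same held for 19 of 28 glycolysis and hypoxia genes (Pfkl 0.52 ± 0.05), 14 of 19 core macrophage genes (Mrc1 1.06 ± 0.13) and 15 of 23 efferocytosis genes (C1qa 1.12 ± 0.14, Stab1 1.05 ± 0.13). They were lower in 19 of 23 NRF2 genes (Nqo1 -1.74 ± 0.11, Prdx1 -1.35 ± 0.08), 18 of 26 stress response genes (Slc7a11 -1.77 ± 0.12) and 12 of 25 fatty acid oxidation genes (Acot2 -1.36 ± 0.12). Adjusted over the list alone these counts were 30, 23, 20, 14 and 16 higher and 19, 19 and 12 lower. Camera called all 9 lists, with adjusted p between 1.48e-18 for the cell cycle and 0.00245 for efferocytosis; with an estimated correlation it called none, the smallest adjusted p being 0.0638 for cholesterol and the largest 0.545 for interferon. Limma called 4726 genes different, 2617 higher and 2109 lower with ACM (1596 and 2608 after TPM scaling, 2271 and 2541 after median scaling).

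Both WT comparisons share their 4 untreated libraries, and shared controls alone give a positive correlation. Fold changes correlated across 11377 genes with r = 0.699, against 0.50 when unchanged groups were simulated against the same controls, and 0.562 when the untreated libraries were split 2 and 2 so that no library was shared; genes are not independent replicates. The covariance was 0.0578 against a simulated 0.0072, a difference of 0.0506. Of the genes called in both, 1012 rose in both, 979 fell in both and 48 went in opposite directions. Independent lists of those sizes would share 350.5 rising and 305 falling genes, but these lists share their controls. With the untreated libraries split, the shared counts were 644.3 rising and 467.5 falling (mean of 6 splits). Independent lists would then share 194.8 and 137.1. Cdkn1c, Procr, Ddit3 and Plin2 were among the shared rises and Mmp8, F13a1, Cbr2 and Fcrls among the shared falls.

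**Figure D3:**
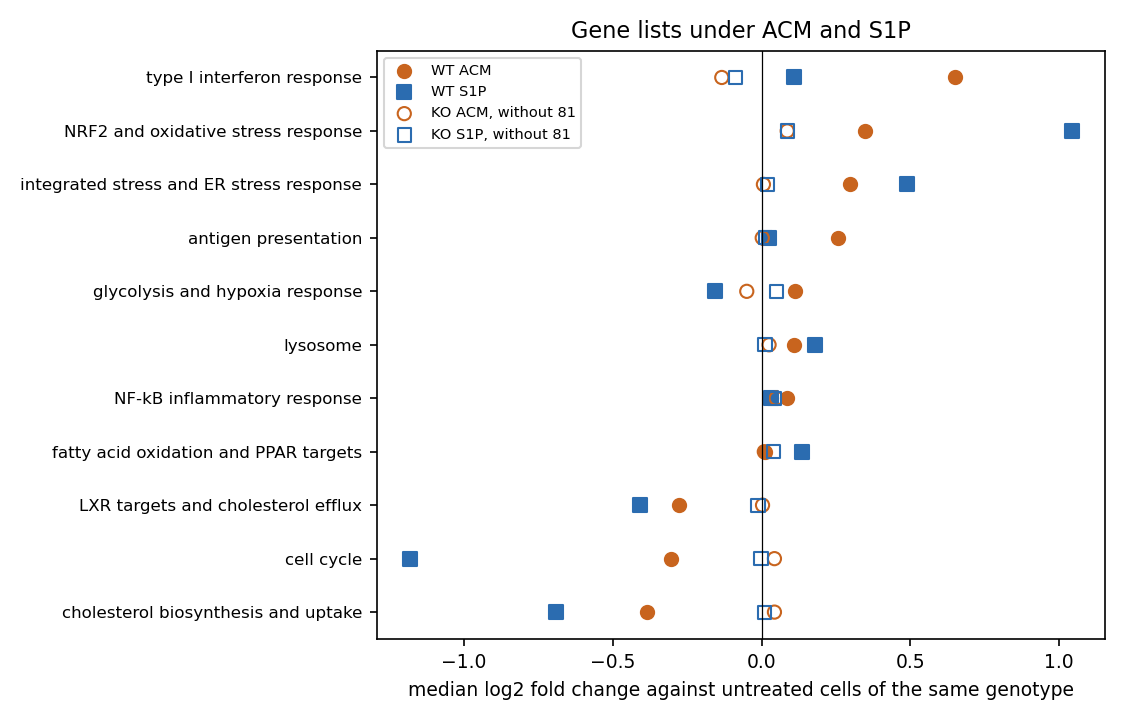
Median log2 fold change over the tested members of the 11 gene lists that camera called for ACM in WT cells, in 4 comparisons with untreated cells of the same genotype. Filled points are WT, open points KO without the library labelled KO untreated 81, circles ACM and squares S1P. The WT S1P medians run from -1.18 to 1.04, while every KO median lies between -0.13 and 0.09.

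In untreated cells the comparison of genotypes depends on the library labelled KO untreated 81. Without it, KO untreated cells had more Treml1 (1.78 ± 0.11), F13a1 (1.23 ± 0.09), Mmp10 (1.27 ± 0.14), the calgranulin S100a9 (1.20 ± 0.21), Ms4a7 (0.97 ± 0.06) and the class II gene H2-Eb1 (0.88 ± 0.09) than WT untreated cells (SE, n = 3 against 4). They had less Lyz2, lysozyme (-1.11 ± 0.10), Lpl, lipoprotein lipase (-0.93 ± 0.04), Cd36, a fatty acid receptor (-0.47 ± 0.04), and Mmp9 (-1.03 ± 0.14). With the library included, Lyz2 was -0.94 ± 0.13, Ms4a7 0.80 ± 0.11, Lpl -0.68 ± 0.14, Thbs1 0.63 ± 0.10, Mertk, a receptor for dead cells, 0.39 ± 0.07 and Scd1 -0.42 ± 0.04, all called. The last 3 were 0.81 ± 0.04, 0.49 ± 0.06 and -0.42 ± 0.04 without it. H2-Eb1 was called with it at 0.61 ± 0.16, but not in 12 of 18 other settings. In that fit F13a1 (0.72 ± 0.28), S100a9 (0.80 ± 0.28), Mmp10 (0.74 ± 0.31), Cd36 (-0.27 ± 0.11) and Mmp9 (-0.45 ± 0.34) were not called (adjusted p = 0.198, 0.142, 0.233, 0.238 and 0.544). Lysosomal genes were higher in 6 of 33 cases (16 adjusted over the list alone), with Tpp1 at 0.16 ± 0.03 and Grn at 0.14 ± 0.03 (0.18 ± 0.03 and 0.12 ± 0.03 without that library), calls lost in 5 and 6 of 19 other settings. Camera adjusted p for them was 1.83e-09 (0.0191 with an estimated correlation), and without that library 8 were higher (camera adjusted p = 4.52e-05, and 0.0509 with an estimated correlation). Granulocyte and progenitor markers were higher in 1 of 8 cases (4 adjusted over the list alone; camera adjusted p = 0.00775, and 0.239 with an estimated correlation). Without that library 4 were higher (6 adjusted over the list alone), with S100a8 at 0.85 ± 0.12 (0.66 ± 0.15 with it) and camera adjusted p = 9.42e-05 (0.0118 with an estimated correlation). Extracellular matrix and fibrosis mediators were higher in 8 of 19 and lower in 1 without that library (9 and 1 adjusted over the list alone), with Mmp13 at 0.79 ± 0.10 (0.35 ± 0.25 and not called with it; camera adjusted p = 0.000342, and 0.0176 with an estimated correlation). With it 1 was higher and camera gave 0.595. The interferon list had a median of 0.17 (camera adjusted p = 9.97e-05, and 0.662 with an estimated correlation) with that library and -0.05 (adjusted p = 0.299, and 0.85 with an estimated correlation) without it. Antigen presentation genes were higher in 5 of 23 cases (7 adjusted over the list alone; camera adjusted p = 9.97e-05, and 0.203 with an estimated correlation). Without that library 7 were higher and 1 lower (8 and 3 adjusted over the list alone), with a camera adjusted p of 0.00381 (0.362 with an estimated correlation). Cell cycle genes had a median of -0.16 with 0 of 30 called (camera adjusted p = 5.49e-05, and 0.642 with an estimated correlation), and of -0.14 with 1 lower without that library (camera adjusted p = 0.00573, and 0.775 with an estimated correlation). Respiratory chain genes had one of -0.05 with 0 of 28 called (camera adjusted p = 0.00204, and 0.57 with an estimated correlation). Without that library theirs was -0.06 with 4 lower (7 adjusted over the list alone; camera adjusted p = 0.000812, and 0.362 with an estimated correlation). LXR targets, with 1 higher and 2 lower of 17, had camera adjusted p = 0.0448 (0.57 with an estimated correlation). Without that library 2 LXR targets were higher and 4 lower, and camera did not call the list (adjusted p = 0.618, and 0.85 with an estimated correlation). Limma called 281 genes, 143 higher and 138 lower in KO, and 928 without that library, 470 higher and 458 lower; with it, TPM scaling gave 37 higher and 157 lower, quantile normalization 156 and 157 and voom 146 and 167.

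The same treatments were then compared within KO cells. ACM lowered 1 gene among 11377, Oas2, an interferon-induced antiviral enzyme (-0.29 ± 0.04, adjusted p = 0.0262), and S1P lowered 1, Dennd4b (-0.18 ± 0.03, adjusted p = 0.0152). Unadjusted limma p was under 0.05 for 1043 genes with ACM and 1167 with S1P (885 and 1025 without the library labelled KO untreated 81). These counts exceed the share of 0.05 of the 11377 genes that unchanged genes would give. Whether small changes or a difference between preparations gave the excess was not tested. Voom on recovered reads, added after the data were seen, called 3 for each. Without the library labelled KO untreated 81 limma called 5 genes for ACM: Rbm3, a cold-inducible RNA-binding protein (0.45 ± 0.05), the nuclear RNA Neat1 (-0.49 ± 0.09), Oas2 (-0.27 ± 0.05) and the predicted genes Gm48583 (0.83 ± 0.14) and Gm49759 (-0.32 ± 0.05), the last 2 named after their values were seen. With that library only Oas2 of these 5 passed. It called 21 for S1P, 3 higher and 18 lower, with Acod1 at 0.35 ± 0.07, Lilrb4a at -0.57 ± 0.09 and Leng8 at -0.41 ± 0.07. With that library these did not pass, Acod1 having the opposite sign (-0.06 ± 0.23), Lilrb4a -0.44 ± 0.10 and Leng8 -0.26 ± 0.10. Genes that moved in WT cells, also named after their values were seen, did not pass: Cdkn1c was -0.09 ± 0.15 with ACM and -0.24 ± 0.15 with S1P, and Procr 0.04 ± 0.15 and 0.08 ± 0.15, without that library. The interferon list had 1 member lower (21 adjusted over the list alone) and a median of -0.33 with ACM (camera adjusted p = 6.95e-22, and 0.473 with an estimated correlation). Without that library 3 were lower over the list alone and the median was -0.13 (camera adjusted p = 8.39e-11, and 0.467 with an estimated correlation). Under S1P its median was -0.29 with the library and -0.09 without it (camera adjusted p = 1.43e-15 and 3.18e-05, and 0.629 and 0.639 with an estimated correlation). NRF2 genes had a median of 0.09 with ACM and 0.09 with S1P, without that library and with 0 members called (camera adjusted p = 1.39e-05 and 0.000168, and 0.467 and 0.568 with an estimated correlation). With it the medians were 0.07 and 0.05 (camera adjusted p = 0.000598 and 0.00408, and 0.772 and 0.723 with an estimated correlation). With quantile normalization ACM called 1 gene higher and 3 lower, and with voom 1 higher and 2 lower.

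Set against WT cells under the same treatment, KO ACM cells had more Ifitm1 (2.60 ± 0.30), F13a1 (2.58 ± 0.28), Mmp8 (2.46 ± 0.30) and S100a8 (1.43 ± 0.15). They had less Mmp9 (-3.12 ± 0.34), Cdkn1c (-2.66 ± 0.16), Acod1 (-1.76 ± 0.23) and Ifit3 (-1.57 ± 0.26) (SE, n = 4 against 4). All 29 type I interferon genes were lower (29 adjusted over the list alone; camera adjusted p = 6.97e-20, and 0.24 with an estimated correlation), with Irf7 at -1.03 ± 0.14. Cholesterol genes were higher in 22 of 24 cases (22 adjusted over the list alone), Fdft1 by 0.68 ± 0.05 (camera adjusted p = 2.89e-21, and 0.005 with an estimated correlation). Granulocyte and progenitor markers were higher in 6 of 8 (6 adjusted over the list alone; camera adjusted p = 3.65e-05, and 0.0401 with an estimated correlation). Under S1P the KO cells had more F13a1 (3.48 ± 0.28), Cbr2 (3.09 ± 0.22), Mrc1 (1.68 ± 0.13) and Stab1 (1.89 ± 0.13). Lower in them were Cdkn1c (-5.61 ± 0.16), Serpinb9b (-4.32 ± 0.16), Procr (-3.30 ± 0.15) and Slc7a11 (-2.45 ± 0.12). All 30 cell cycle genes and all 24 cholesterol genes were higher and 21 of 23 NRF2 genes lower (30, 24 and 21 adjusted over the list alone). Camera gave these 3 lists adjusted p = 1.31e-15, 8.1e-18 and 9.12e-16, and adjusted p = 0.313, 0.0121 and 0.144 with an estimated correlation. Limma called 3186 genes under ACM, 1421 higher and 1765 lower in KO (1658 and 964 after TPM scaling), and 5958 under S1P, 3066 higher and 2892 lower (2212 and 3113 after TPM scaling, 2706 and 3335 after median scaling). Of these, 1757 under ACM and 4854 under S1P were also called in the opposite direction between treated and untreated WT cells. The differences therefore include the WT change with treatment. Both comparisons use the same treated WT libraries, which by itself favours opposite directions.

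The interaction terms tested whether the response itself differed between genotypes. For ACM the 10 smallest p-values included Scd1 (0.71 ± 0.05), Cdkn1c (-2.79 ± 0.23), Aacs, a ketone-using enzyme of lipid synthesis (0.61 ± 0.05), Cpt1a (-0.72 ± 0.07) and Fasn (0.79 ± 0.08), where a negative value means that the log2 fold change was lower in KO than in WT cells (SE, n = 4 in each of 4 groups). The interaction was negative for 28 of 29 type I interferon genes, with Irf7 at -1.44 ± 0.20, and for 14 of 23 NRF2 genes. It was positive for 19 of 24 cholesterol genes, a list that fell with ACM in WT cells (29, 15 and 20 adjusted over the list alone). Camera adjusted p was 4.54e-23, 6.52e-08 and 3.09e-20, and with an estimated correlation adjusted p was 0.158, 0.226 and 0.00696. Without the library labelled KO untreated 81 these lists counted 28 and 12 negative and 20 positive (camera adjusted p = 7.32e-34, 3.84e-07 and 1.21e-21, and 0.0401, 0.268 and 0.00528 with an estimated correlation). Without it Scd1 was 0.71 ± 0.06, Cdkn1c -2.61 ± 0.20, Aacs 0.61 ± 0.05, Cpt1a -0.67 ± 0.06, Fasn 0.74 ± 0.07 and Irf7 -1.22 ± 0.12. For S1P the 10 smallest included Cdkn1c (-5.73 ± 0.23), Aacs (1.02 ± 0.05), Creg1 (-1.59 ± 0.08), Prdx6 (-1.75 ± 0.09) and Prdx1 (-2.02 ± 0.11). The interaction was positive for all 30 cell cycle and all 24 cholesterol genes, which fell with S1P in WT cells, and negative for 20 of 23 NRF2 genes (30, 24 and 21 adjusted over the list alone). Camera gave adjusted p = 7.66e-18, 1.75e-18 and 3.97e-17, and adjusted p = 0.301, 0.0101 and 0.122 with an estimated correlation. Without that library the counts were 30, 24 and 20, camera adjusted p 9.32e-17, 1.19e-18 and 2.56e-16, and with an estimated correlation 0.259, 0.0102 and 0.115. Without it Cdkn1c was -5.56 ± 0.20, Aacs 1.01 ± 0.05, Creg1 -1.57 ± 0.09, Prdx6 -1.72 ± 0.10 and Prdx1 -1.96 ± 0.11. Limma called 1940 interactions for ACM, 843 positive and 1097 negative (1696 without the library labelled KO untreated 81; 1499 positive and 436 negative after TPM scaling). For S1P it called 4772, 2564 positive and 2208 negative (4716 without that library; 2105 and 1679 after TPM scaling, 2218 and 2662 after median scaling). Of the 2511 genes ACM changed in WT cells, 1662 (66.2%) had a called interaction and 24.3% had the same sign in KO cells. Without that library these were 1526 of 2828 (54%) and 39.2%. For S1P they were 4498 of 5964 (75.4%) and 44.9%, or 4470 of 6177 (72.4%) and 50.4% without it. The slope of KO on WT fold changes over genes called in either genotype was -0.22 for ACM and -0.034 for S1P, and -0.061 and -0.002 without that library, so their size rests on it.

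**Figure D4:**
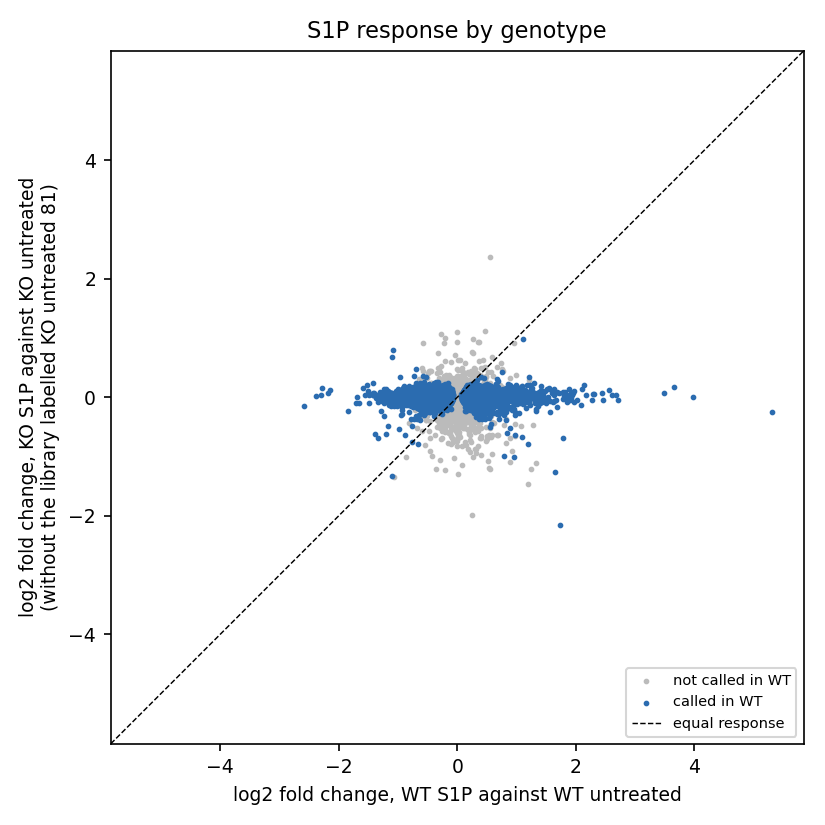
Log2 fold change with S1P in KO cells (vertical, without the library labelled KO untreated 81) against that in WT cells (horizontal) for 11377 genes, each point a gene and both axes to the same scale. Genes called in WT are darker and the dashed line marks equal response. WT values reach 5.32 for Cdkn1c while the slope over called genes is -0.002.

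Direct comparison of the treatments within KO cells called 4 genes, all higher with ACM than with S1P. They were Fos, an immediate early transcription factor (0.47 ± 0.08), the chemokine Cxcl2 (0.42 ± 0.07), Lilr4b, a receptor of myeloid cells (0.40 ± 0.07), and Tcirg1, a subunit of the proton pump (0.24 ± 0.04) (SE, n = 4 against 4). Limma gave adjusted p = 0.0335 for each, while voom called 5. An unadjusted limma p under 0.05 was found for 775 genes, more than the share of 0.05 that unchanged genes would give. Without the library labelled KO untreated 81, which enters only the shared error here, limma called 28, 24 higher and 4 lower. Glycolysis and hypoxia genes had a median of -0.09 with 0 of 28 called (6 lower adjusted over the list alone; camera adjusted p = 6.13e-13, and 0.128 with an estimated correlation). The KO fold changes for the 2 treatments correlated with r = 0.553 across genes, against 0.507 simulated for unchanged groups with shared controls and 0.064 with the controls split, and shared 0 called genes, with 1 gene called in each by limma. Without that library r was 0.540 against a simulated 0.575.

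Of the 5 receptors for S1P, S1pr1 and S1pr2 passed the filter. S1pr1 had an FPKM of 34.3 ± 2.55 in WT untreated and 37.5 ± 1.25 in KO untreated cells without the library labelled KO untreated 81 (SD, n = 4 and 3), and S1pr2 11.9 ± 0.351 and 11.6 ± 0.364. S1pr1 fell with S1P in WT cells (-0.21 ± 0.05, limma adjusted p = 0.00142; exact permutation p = 0.0571) and rose with ACM (0.15 ± 0.05, limma adjusted p = 0.0337; exact permutation p = 0.0286). The rise was lost in 8 of 19 other settings, down to 0.04 with TPM scaling. S1pr2 rose with both (0.40 ± 0.05 and 0.30 ± 0.05). S1pr4 reached at most an FPKM of 1.15 in any library, S1pr3 0.0805 and S1pr5 0.0609, and these 3 were not tested. Of the S1P metabolism genes, Sphk2, a kinase that makes S1P, rose by 0.65 ± 0.07 and Plpp3, a lipid phosphatase, by 1.27 ± 0.15 with S1P in WT cells. As a list, 7 of 17 rose and 6 fell with S1P and 5 rose and 2 fell with ACM (7, 6, 7 and 5 adjusted over the list alone; camera adjusted p = 0.843 and 0.547).

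The remaining lists moved both ways or little in WT cells. In the lipid-associated macrophage program, to which Trem2 belongs, 10 of 24 members rose and 6 fell with ACM, and 12 rose and 8 fell with S1P (camera adjusted p = 0.267 and 0.322), with Gpnmb at 0.44 ± 0.04 and Cd63 at 0.53 ± 0.05 under S1P. Alternative activation genes rose in 6 and fell in 2 of 19 cases with ACM, and in 7 and 6 with S1P (camera adjusted p = 0.447 and 0.897), with Arg1, arginase, at 0.77 ± 0.15 under ACM. Efferocytosis and core macrophage genes under ACM counted 6 and 6 higher and 7 and 5 lower (camera adjusted p = 0.364 and 0.922), and antigen presentation genes under S1P 8 and 2 (camera adjusted p = 0.182). Respiratory chain genes counted 1 higher and 2 lower of 28 with ACM and 4 and 11 with S1P, and matrix mediators 3 and 6 of 19 with ACM and 9 and 8 with S1P (camera adjusted p = 0.559, 0.431, 0.288 and 0.897). NF-kB genes under S1P counted 8 higher and 9 lower (camera adjusted p = 0.897).

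Markers of other cell types were looked for because ACM comes from hepatocytes and marrow holds other lineages. Of 24 hepatocyte and liver epithelium markers 3 passed the filter, Trf, Afp and Apoa2, none called with ACM (camera adjusted p = 0.724), while Afp rose by 0.78 ± 0.08 with S1P in WT cells (camera adjusted p = 0.897 for the list). The hepatocyte transcripts Alb and Apoa1 reached at most 0.0377 and 0.0488 FPKM in any library. None of 20 fibroblast markers passed the filter, and of 26 lymphocyte, mast cell and erythroid markers only Ighm did. Granulocyte and progenitor markers counted 0 higher and 1 lower of 8 with ACM and 0 and 3 with S1P in WT cells (camera adjusted p = 0.076 and 0.445), monocyte markers 5 and 2 of 13 and 4 and 5 (0.378 and 0.897). Dendritic cell markers counted 2 and 0 of 4 and 1 and 0 (0.193 and 0.897), and osteoclast markers 3 and 0 of 10 and 6 and 3 (0.267 and 0.182), Itgb3 rising by 1.39 ± 0.16 with S1P. Of the sex-linked transcripts, Xist reached at most 0.0113 FPKM in any library and Ddx3y averaged 14.7 to 16.7 in the 6 groups, with 0 of 4 called with ACM and 1 with S1P (camera adjusted p = 0.547 and 0.897).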

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

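All tests of explanations in this part were chosen only after the result was seen, while the interaction tests were chosen before. In 72 tests, of 12 measures in each of 6 groups of 4 libraries, 6 tests found a library far from the others by Dixon's ratio, where chance gives about 1 in 20. These fell in 2 groups, and 4 of the 6 concern the library labelled KO untreated 81. It lay at 0.775 on the first principal component, where the other KO untreated libraries lay at -11.2 to -11.0, and at 12.6 on the second, where they lay at -7.28 to -5.52. Its Trem2 FPKM was 79.6 against 35.7 to 40.2. Apart from it, the library WT S1P 25 had 10681 genes at an FPKM of 1 against 10773 to 10791 in the other WT S1P libraries, and WT S1P 26 had a Treml1 FPKM of 2.22 against 1.59 to 1.70.

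The first pattern weighed is this library. On 13 genes that differ between the genotypes in both treated arms and that neither treatment moves in WT cells, scaled so that treated KO libraries average 0 and treated WT libraries 1, it had a median of 1.022, where the other KO untreated libraries had -0.016 to 0.113. Among the 13 were mt-Tg, mt-Nd3, Gm28438, Ifi208 and Treml1, which also appear in the third pattern below. The scale therefore does not separate the knockout from a colony or substrain difference. RNA mixed from both genotypes in similar parts is argued against by its lower quartile of 0.996, above the lowest WT median. A swap with a WT library is argued against because the lowest WT median was 0.930. A wrong label on cells or RNA of WT macrophages is consistent with the value of 1.022, which could have been lower, and stays open with an outside sample or a culture of the other genotype. On a scale of 41 ACM genes it lay at 0.762, between WT untreated (0) and WT ACM (1), so it did not match WT untreated libraries either.

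The second pattern is the near absence of called responses in KO cells. Noise from the library labelled KO untreated 81 is argued against by the 5 genes ACM changed and the 21 S1P changed without that library, against 2511 and 5964 in WT cells. A response of WT size missed by the test is argued against by slopes of KO on WT fold changes of -0.061 for ACM and -0.002 for S1P without it. Separate handling of KO cultures, or a reagent that did not act in them, cannot be told apart from genotype: no batch is labelled, and the highest S1P scale position of a KO S1P library was 0.085, where WT S1P libraries averaged 1 and ran from 0.714 (WT S1P 25) to 1.19 (WT S1P 27). A response that needs Trem2 stays open as a hypothesis.

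The third pattern is the set of 415 genes other than Trem2 that differed between genotypes in the same direction in all 3 treatments without the library labelled KO untreated 81. With that library 74 genes did, Trem2 included. DNA carried along with the targeted locus is argued against for the set, since 0.96% of the 415 genes lay within 10 Mb of Trem2 against 1.08% of all tested genes (Fisher's exact p = 1). A colony or substrain difference cannot be told apart from the knockout: without that library, 12 genes had a mean FPKM of at least 1 in all 3 groups of 1 genotype and at least 4 times less in each group of the other. Among them, named after their values were seen, were Marco, higher in WT cells, and Ccl22, Ifi208 and Treml1, higher in KO cells. They also held the neighbouring mitochondrial genes mt-Tg (FPKM 0 in each WT group, 5.9 to 7.99 in KO groups), mt-Nd3 (3.15 to 3.66 and 20.5 to 23.1) and mt-Tr (0 to 0.48 and 2.22 to 4.66). Gm28438, an unprocessed pseudogene on chromosome 1, went the other way (42.6 to 50.4 and 2.89 to 5.94). So did Gm42031, a long noncoding RNA gene on chromosome 8 (26.4 to 43.9 and 0.00608 to 0.193). Its FPKM was 37.9 in the library labelled KO untreated 81. Of the 12 genes, 3 were higher in WT cells, on 2 chromosomes, and 9 in KO cells, on 7, counting the mitochondrial genome. FPKM does not show sequence, so a difference in DNA was not tested.

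The genotypes differed in their response by the interaction test for 1940 genes with ACM and 4772 with S1P. With ACM these included Scd1 (0.71), Cdkn1c (-2.79), Aacs (0.61), Cpt1a (-0.72), Fasn (0.79) and Irf7 (-1.44). With S1P they included Cdkn1c (-5.73), Aacs (1.02), Creg1 (-1.59), Prdx6 (-1.75), Prdx1 (-2.02) and Trem2 (-0.62). Without the library labelled KO untreated 81 Trem2 was -0.36 ± 0.06 with S1P (adjusted p = 9.49e-05). With ACM the Trem2 interaction did not pass, at -0.43 ± 0.20 with that library and -0.17 ± 0.06 without it (limma adjusted p = 0.154 and 0.065).

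Other splits of the same libraries were counted for each comparison. For 5 comparisons only the real split of 35, 1 split, gave as many genes, which argues against a random assignment of these libraries. These are WT ACM (2511 genes, highest other split 1), WT S1P (5964 and 2649), KO ACM against WT ACM (3186 and 1), KO S1P against WT S1P (5958 and 2387) and WT ACM against WT S1P (4726 and 2423). For both interactions only the real split of 100 gave as many genes (1940 and 2 for ACM, 4772 and 8 for S1P). Those splits put WT and KO libraries, which differ, in the same group and so widened the spread. They cannot exclude chance for the interactions. No split can exclude a difference between cultures or preparations, which the labels do not give. The highest other splits with 2649, 2387 and 2423 genes each exchange WT S1P 25 for libraries of the other group, which points to a structure of the WT S1P samples. Chi-square per degree of freedom between these samples ran from 3.07 (27 and 28) to 23.5 (25 and 27). KO groups also held uneven pairs, to a lesser degree. In KO ACM it ran from 2.81 (85 and 86) to 12.1 (85 and 87), and in KO S1P from 2.845 (92 and 94) to 9.44 (91 and 94). Chance cannot be excluded for KO ACM (1 gene, 4 of 35 splits, highest other 1), KO S1P (1 gene, 4 of 35, highest other 2) and KO ACM against KO S1P (4 genes, 2 of 35, highest other 5). The same holds for KO untreated against WT untreated (281 genes, 3 of 35, highest other 369), where that split puts the library labelled KO untreated 81 with the WT libraries and a WT library in its place.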

How the results depend on the processing

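Tests without the library labelled KO untreated 81 and with voom on recovered reads were chosen only after the data were seen. The counts of genes in WT ACM (1891 to 3363), WT S1P (4544 to 6177), KO against WT under ACM (2620 to 4117) and S1P (4498 to 6252), the interactions (1426 to 2522 and 3782 to 4880) and WT ACM against S1P (3769 to 4993) stayed within 1.5 times in all settings run, and with any 1 library left out. No paired analysis was possible because no replicate number occurs in 2 groups. Robust empirical Bayes was not run for the gene lists, for which camera has no such option. The cause of the changes below was not tested, except where fewer libraries or genes were used.

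KO ACM called 1 gene, and 2 with no filter, 8 with the filter at FPKM 5, 0 with TPM scaling, 4 with quantile normalization, 3 with median scaling, 13 with arrayWeights, 3 with voom, 5 without the library labelled KO untreated 81 and 0 with only its own groups. Leaving out libraries gave 0 (without KO untreated 80 or 82, or KO ACM 85) to 5. KO S1P called 1, and 3 with the filter at FPKM 5, 0 with TPM scaling, 39 with arrayWeights, 3 with voom, 21 without that library and 0 with only its own groups. Leaving out libraries gave 0 (KO S1P 93 or 94) to 21, with 4 without KO untreated 79 and 3 without 82. KO untreated against WT untreated called 281, and 1186 with arrayWeights, 928 without that library and 33 with only its own groups. With 1 library left out it called 112 (KO untreated 80), 120 (82), 132 (79), 129 (WT untreated 4), 164 (1), 169 (2), 173 (3) or 928 (KO untreated 81). KO ACM against KO S1P called 4, and 0 with no filter, TPM scaling, quantile normalization or median scaling, 46 with arrayWeights, 28 without that library and 16 with only its own groups. With 1 library left out it called 0 (KO ACM 86 or 88, KO S1P 91, 92 or 93), 1 (KO ACM 87) or at most 3. The count shared by ACM and S1P in KO was 0, 1 with no filter, the filter at FPKM 5, quantile normalization, median scaling or without that library, and 2 with arrayWeights.

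Trem2 kept its direction in all calls. The difference with ACM in WT cells (0.21) was 0.09 with TPM scaling (adjusted p = 0.652) and 0.14 with quantile normalization (adjusted p = 0.519). It passed with arrayWeights (0.21, adjusted p = 0.0463), without that library (0.21, adjusted p = 0.000858) and with only its own groups (0.21, adjusted p = 0.00302), and its adjusted p ran from 0.000858 to 0.652 over the settings that keep all libraries of the groups compared. The rise with S1P (0.41) no longer passed with no filter (adjusted p = 0.0568) or without WT S1P 27 (0.38, adjusted p = 0.0545), leave-out values running from 0.38 to 0.44. With only their own groups, KO untreated against WT untreated (-0.75, adjusted p = 0.168) and the S1P interaction (-0.62, adjusted p = 0.0539) did not pass, nor did the interaction with no filter (-0.62, adjusted p = 0.0507). WT ACM against S1P (-0.20) passed without that library (adjusted p = 0.000668) and with only its own groups (adjusted p = 0.00645).

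With an estimated correlation between genes, the lists called fell from 11 to 3 for WT ACM, 10 to 1 for WT S1P, 4 to 0 for KO ACM and for KO S1P, and 7 to 1 for KO against WT untreated. They fell from 12 to 2 under ACM, 10 to 1 under S1P, 11 to 1 for each interaction, 9 to 0 for WT ACM against S1P and 4 to 0 for the same in KO. KO ACM called 7 lists with no filter and 9 with voom, KO S1P 2 without KO untreated 80 and 6 as the highest with a library left out, and KO ACM against S1P 2 with the filter at FPKM 5 and 9 with only its own groups. The slope of KO on WT fold changes was -0.22 for ACM, -0.099 with arrayWeights and -0.061 without that library, from -0.282 to -0.061 with a library left out. For S1P it was -0.034, -0.005 with arrayWeights and -0.002 without that library, from -0.048 to -0.002 with a library left out.

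Reversed were Acod1 with S1P in KO cells, -0.06 ± 0.23 with and 0.35 ± 0.07 without that library, from -0.252 to 0.350 with a library left out. So was the interferon list between untreated genotypes, with medians of 0.17 and -0.05, from -0.05 to 0.246 with a library left out. Of 164 named gene values, 17 lost their call in at least 1 setting and 12 gained it.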

Other observations

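Other gene groups separated the genotypes under treatment, and these differences can include the WT change with treatment. With ACM, KO cells had more transcript than WT cells for 15 of 17 LXR targets and less for 1 (15 and 1 adjusted over the list alone), and camera gave adjusted p = 9.03e-08 (0.055 with an estimated correlation). NRF2 genes were lower in 16 of 23 cases (18 adjusted over the list alone; camera adjusted p = 3.7e-07, and 0.28 with an estimated correlation) and glycolysis and hypoxia genes in 16 of 28 (18 adjusted over the list alone; camera adjusted p = 3.7e-07, and 0.24 with an estimated correlation). With S1P, 20 of 26 integrated stress genes were lower in KO and 4 higher (20 and 4 adjusted over the list alone; camera adjusted p = 6.01e-06, and 0.313 with an estimated correlation). Efferocytosis genes were higher in 15 of 23 and lower in 5 (15 and 5 adjusted over the list alone; camera adjusted p = 0.00131, and 0.313 with an estimated correlation). Of the 4 sex-linked transcripts tested, 3 were higher in KO ACM than in WT ACM cells (4 adjusted over the list alone; camera adjusted p = 0.0287, and 0.28 with an estimated correlation), and Ddx3y was present in every group, at 16.7 FPKM in KO ACM and 14.7 in WT ACM cells.

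The difference between untreated KO and WT cells was also set against the response of WT cells to each treatment, without the library labelled KO untreated 81 and after the data were seen. Of 441 genes called both between the untreated genotypes and with ACM in WT cells, 247 went in opposite directions, and with S1P 288 of 652 did. With that library these were 8 of 133 and 32 of 191. Splitting the WT untreated libraries so that none was shared, the fold changes correlated across genes with a mean r of 0.026 for ACM and 0.104 for S1P, where genes are not independent replicates.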
